A study of Mus musculus with 12 samples.

How the data were processed

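Omni-ATAC-seq libraries of sorted splenic germinal center B cells were analysed from Pbrm1+/+ (WT) and Pbrm1-/- (HOMO) mice, with 3 libraries in each of 4 groups (WT CB, WT CC, HOMO CB and HOMO CC). Per the labels' protocols, DNA was purified with a Zymo kit and amplified with KAPA HiFi polymerase. The deposited table holds a raw read count for each of 12 libraries in each peak, made by the authors on mm10. The submitters' processing notes name BWA, FastQC, deepTools and R 4.2.1 without giving their roles. The peak caller, the counting tool, the handling of duplicates and of the Tn5 offset, and whether libraries were pooled for peak calling are not given in the sources used here. The values were whole numbers in 68689 peaks of 501 bp on 20 chromosomes, 67159 of them autosomal.

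Groups and replicate numbers were taken from the labels. The mean count per peak ran from 93.6 to 664 between libraries and the common biological coefficient of variation was 0.142. Between replicates the chi-square per degree of freedom of counts was 2.28 to 7.67, above the 1 of counting error alone. The median standard error of a log2 fold change was 0.20.

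The tests, gene lists, naming rule and alternatives were fixed before the data were examined, except those named as later choices in the closing section. Among the exceptions are the 6 Mb zone around Pbrm1 and the contrast of gene-end with other peaks at log2 CPM of 2 to 5. Counts were normalized with TMM factors (0.954 to 1.05) and fitted with edgeR 4.0.16 under R 4.3.3, with 1 mean per group over 12 libraries, robust quasi-likelihood dispersions and two-sided F tests. The filter filterByExpr removed no peak. Peaks were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were HOMO against WT in CB and in CC, the difference of these effects, and CC against CB in WT and in HOMO. CPM values use TMM factors, and log2 CPM a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 served as alternative tests. Values were handled with the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

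Each peak was assigned to the nearest of 21031 protein-coding gene spans of a RefSeq table (GRCm38.p6) within 50000 bp, which placed 63977 peaks (93.1%) at 14134 genes. The table used carries no strand. The planned nearest transcription start and promoter classes were therefore replaced by the nearest gene span and by a gene-end class, with the midpoint within 1 kb of either end of a gene. By this class 16032 peaks were gene ends, 31683 lay elsewhere within a gene span and 20974 were intergenic. The planned motif tests and GC corrections need a genome sequence and were not run.

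A total of 17 gene lists was tested with camera at a preset correlation of 0.01, with adjustment over the lists within a contrast. They were the light zone program, dark zone program, germinal center transcription factors, memory precursor genes, plasma cell genes, BAF and PBAF subunits, interferon response, antigen presentation, B cell receptor signalling, migration receptors, cell cycle and apoptosis, AP-1 and immediate early factors, and markers of T cells, naive and follicular B cells, myeloid cells, erythroid cells and natural killer cells. Camera with an estimated correlation and fry were run beside it. Some genes stand in 2 lists, such as Bach2, Ccnd3 and Foxp1, and the naive B cell list shares genes with the memory precursor list.

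Named peaks followed a rule. For the genotype effects and for CC against CB in WT, it took the 8 called peaks of smallest p in each direction, 1 per gene, autosomal, with an average log2 CPM of at least 1 and with groups that did not overlap. It also took up to 3 called peaks from each list, 3 peaks per direction for the difference of effects, and the gene-end peaks of Pbrm1, Bcl6, Prdm1, Irf4, Myc, Cxcr4, Cd83, Cd86, Foxo1 and S1pr2 and the peak nearest Ccr6. Some genes that the rule names are not used here.

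Whether equal replicate numbers mark pairs was checked on deviations from group means. Within a genotype, same-numbered CB and CC libraries correlated at 0.21 to 0.52 (6 pairs) and different-numbered ones at -0.34 to 0.12 (12 pairs), so a fit with a term for genotype and number is given beside the CC against CB results. Across genotypes, same-numbered libraries correlated at -0.01 to 0.40 (12 pairs) and others at -0.30 to 0.18 (24 pairs), and they were not treated as pairs. Depth varied with the number, with library 3 the deepest of each group, and principal component 3 (16.0% of variance) followed log2 library total (Pearson's r = -0.92). Whether shared depth gives part of the same-number correlations was not tested.

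The test was checked on simulated data with 200 changed peaks among 68689 and the fitted means, dispersions and depths. In CB it called 40% of peaks changed 1.5-fold, 62% of those changed 2-fold, 92% of those changed 3-fold and 92% of those changed 4-fold, and in CC 22%, 50%, 88% and 96%. Of the unchanged peaks it called 14 in CB, 16 in CC and 1 for the difference of effects, and it called a shifted list of 163 peaks in both populations. That list had estimated medians of 0.29 in CB and 0.32 in CC, larger than those of the lists called higher below. Peaks were drawn independently of each other, so the simulation does not check the preset correlation of camera.

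Correlations along the CC against CB axis were set against 100 simulated data sets with no genotype effect. Alternatives covered scaling (RLE, library size only, loess with a span of 0.3), the test, the filter (none, or a CPM of 1 in 6 libraries), the groups fitted, chromosomes, thresholds, replicate terms, gene windows (up to 1e+05 bp), gene-end limits (3000 bp) and leaving out each library.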

Results

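Chromatin accessibility was measured by Omni-ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. The cells were germinal center B cells sorted from spleens of C57BL/6 mice aged 8 to 10 weeks. Such cells are antigen-activated B cells that divide, mutate their antibody genes and are selected for affinity. The mice carried either intact Pbrm1 (Pbrm1+/+, labelled WT) or its homozygous knockout (Pbrm1-/-, labelled HOMO). The names of the count columns begin with Pbrm1AID, which the sources used here do not explain, so how the allele was made is not known. Pbrm1 encodes a subunit specific to PBAF, a chromatin remodeler of the SWI/SNF family. Each genotype had 2 sorted populations, which the labels call CB and CC without spelling the letters out, and each of the 4 groups had 3 libraries, 12 in all. The labels do not say that each library came from a separate mouse, so the p-values below measure the spread between these libraries, which could be partly technical.

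The deposited table held read counts in 68689 peaks of 501 bp, of which 1530 lay on the X chromosome. Library totals in peaks ran from 6431354 counts in HOMO CC 1 to 45590454 in HOMO CB 3, a 7.09-fold range. The HOMO libraries numbered 1 were the 2 shallowest, with 7679509 counts in HOMO CB 1. At a peak inside Xist, the gene of the RNA that coats the inactive X chromosome, WT CB 2 had 0.458 CPM and WT CC 2 had 0.782 CPM (peak_68094). WT CB 1 and WT CC 1 had 6.39 and 4.74 CPM there, and the other 8 libraries 8.58 to 17.2 CPM. The sex of the mice is not given in the sources used here.

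**Figure D1:**
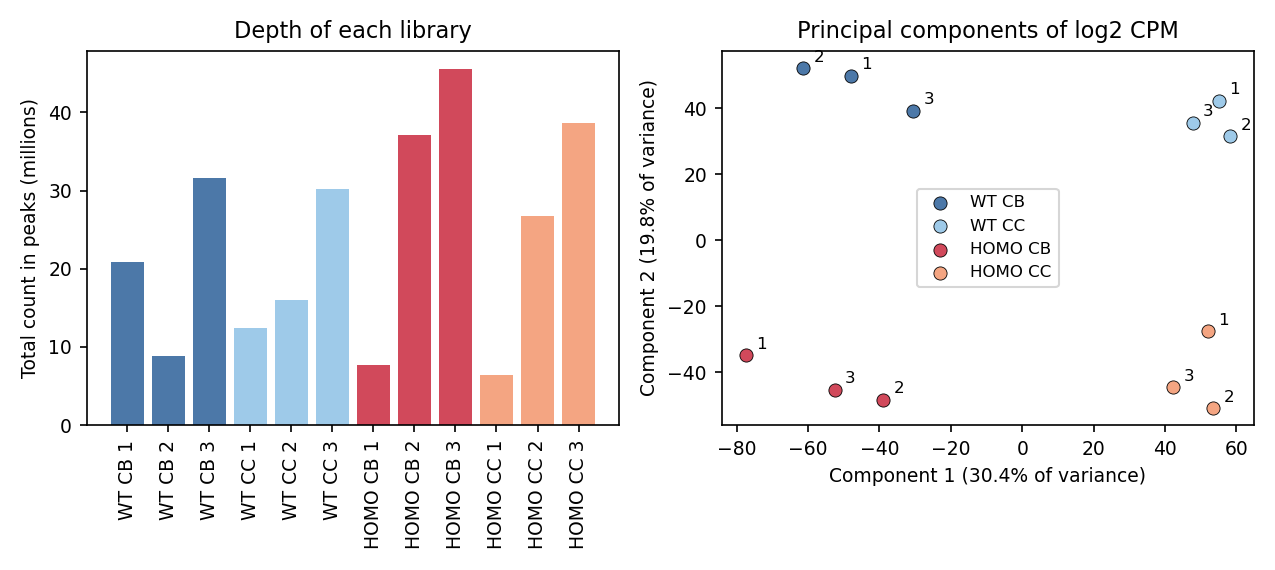
Left, total count in peaks of each library (bars). Right, the first 2 principal components of log2 CPM, with 1 point per library, numbered by replicate and coloured by group; CC and CB libraries separated on component 1 (30.4% of variance) and WT and HOMO libraries on component 2 (19.8%).

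The Pbrm1 gene was examined first. The peak at the lower-coordinate end of Pbrm1 (peak_52811, chromosome 14, 31019227 to 31019727) was open in every group, with 31.6 ± 6.78 CPM in WT CB and 30.7 ± 4.84 CPM in HOMO CB (mean ± SD, n = 3). Its log2 fold change was -0.04 in CB (SE 0.18, adjusted p = 0.931) and -0.09 in CC (SE 0.18, adjusted p = 0.855). A weaker peak inside Pbrm1 (peak_52812) had log2 fold changes of 0.67 in CB (adjusted p = 0.27) and 0.63 in CC (adjusted p = 0.347), neither of which passed the test. Which part of Pbrm1 is deleted is not given in the sources used here, so neither peak checks the genotype labels.

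The first comparison asked where loss of Pbrm1 changed accessibility in CB. Most changes were losses: 2643 peaks fell and 535 rose in HOMO CB, assigned to 2134 and 429 genes. The smallest p-value belonged to a peak inside Wdfy4, a gene known for cross-presentation by dendritic cells (chromosome 14, 33189744 to 33190244). It went from 45.4 ± 4.24 CPM in WT CB to 12.2 ± 2.42 CPM in HOMO CB (log2 fold change -1.86, SE 0.13, adjusted p = 4.3e-07). Named losses on other chromosomes included a peak at an end of Inka2 (20.6 ± 1.03 to 9.05 ± 1.47 CPM, -1.22) and a peak inside Thra, the gene of a thyroid hormone receptor (10.3 ± 1.14 to 3.93 ± 0.457 CPM, -1.36). Named gains there included a peak inside Nsun3, the gene of a mitochondrial tRNA methyltransferase (5.2 ± 0.679 to 12.5 ± 0.72 CPM, 1.29). Another lay 15390 bp from Ccnc, which encodes cyclin C (3.52 ± 0.59 to 9.5 ± 0.536 CPM, 1.41).

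Of the gene lists fixed for these cells, the dark zone program, made of genes of the proliferating germinal center compartment, was higher in HOMO CB. Of its 166 peaks 7 rose, 2 fell and 157 did not pass the test, with a median log2 fold change of 0.16 (camera adjusted p = 0.000799, and adjusted p = 0.0122 with an estimated correlation). Its gene-end peaks alone had a median of -0.10 and were not called (camera adjusted p = 0.148). Camera set them against all other peaks. Gene-end peaks in general were lower in CB, with medians of -0.28, -0.16 and -0.05 at log2 CPM of 3 to 4, 4 to 5 and 5 to 6. That test therefore cannot tell a reversal of the list from the class. Adjusted over the list alone, 10 of its peaks rose and 3 fell. Its rising peaks included 2 neighbouring sites inside Ccnd3, which encodes a D-type cyclin of dividing germinal center cells (18.6 ± 1.79 to 28.8 ± 1.5 CPM, 0.62, and 14.1 ± 0.84 to 22.4 ± 0.79 CPM, 0.67). Another lay inside Nusap1, the gene of a spindle protein (0.975 ± 0.326 to 3.37 ± 0.301 CPM, 1.7).

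Peaks of germinal center transcription factors were also higher as a set in CB, with a median of 0.13 (camera adjusted p = 0.000427). That call was lost with an estimated correlation (adjusted p = 0.652). Of 633 peaks 10 rose and 2 fell, and 1 and 0 when adjusted over the list alone. Those that rose included a site 18717 bp from Pou2af1, a B cell coactivator (0.91), and sites inside Foxp1 (0.53) and Ebf1, a B cell identity factor (1.59). B cell receptor signalling peaks had a median of 0.07 (4 of 428 rose and 3 fell, camera adjusted p = 0.0123), a call lost with an estimated correlation (adjusted p = 0.719). Adjusted over the list alone, 0 of them passed with edgeR.

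The interferon response list leaned the other way in CB, with 8 of 111 peaks lower, 0 higher and a median of -0.10. It did not pass camera (adjusted p = 0.0654), while fry, which tests the list without comparing it with other peaks, gave an adjusted p of 0.00745. For the lists that camera called in CB, fry gave adjusted p of 0.00042 for the dark zone, 0.162 for transcription factors and 0.562 for B cell receptor signalling. At gene-end peaks alone camera called it lower in CB (median -0.21, adjusted p = 0.000707) and in CC (-0.17, adjusted p = 0.00264), and did not call the transcription factor and B cell receptor lists in CB (adjusted p of 0.18 and 0.533) or in CC (0.116 each). Each gene-end test set a list's gene-end peaks against all other peaks, most of them not gene ends. Gene-end peaks were lower as a class (at log2 CPM of 3 to 4, median -0.28 in CB and -0.25 in CC). These tests therefore cannot separate a list from its class, for this list or for the natural killer markers below. Over all its peaks with an estimated correlation the interferon list had an adjusted p of 0.384 in CB and 0.467 in CC, and after subtraction of class and level medians its median in CB was -0.058 (SE 0.041 over peaks taken as independent, camera adjusted p = 0.29). Natural killer cell markers were also called lower at gene-end peaks in CC (median -0.38, adjusted p = 0.0429), and over all their peaks without HOMO CC 3 (-0.25, adjusted p = 0.0266), with an adjusted p of 0.467 under an estimated correlation. The lower peaks included a site 16596 bp from Irf1, an interferon-induced transcription factor (24.8 ± 2.44 to 15.3 ± 1.68 CPM, -0.72). Others lay inside Usp18, a brake on interferon signalling (-1.03), and at an end of Ddx58, which encodes the RNA sensor RIG-I (-1.22). Plasma cell genes had 7 of 164 peaks lower and 0 higher, among them a peak inside Sdc1, the gene of the plasma cell surface proteoglycan syndecan (9.28 ± 2.19 to 4.41 ± 1.6 CPM, -1.18). The cell cycle and apoptosis list had 9 of 253 peaks lower and 3 higher. Its lower peaks included a site 5243 bp from Pmaip1, which encodes the death-promoting protein Noxa (-1.52). Among BAF and PBAF subunit genes 3 of 253 peaks fell and 0 rose. They lay inside Dpf1 (7.73 ± 0.26 to 3.14 ± 1.03 CPM, -1.42) and at ends of Dpf2 (9.46 ± 0.499 to 4.68 ± 0.516 CPM, -1.02) and Brd7, another PBAF-specific subunit (-0.69). The plasma cell, cell cycle and subunit lists did not pass camera in CB (adjusted p of 0.876, 0.876 and 0.575). Over all peaks 4.63% were called in CB and 83.2% of those calls were lower. More losses than gains among so few calls is thus not particular to these 3 lists. Adjusted over the list alone, the counts higher and lower were 0 and 9 for interferon, 0 and 5 for plasma cells, 3 and 10 for the cell cycle and 0 and 2 for the subunits.

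The remaining lists were not called in CB with all libraries. Their medians were 0.01 for the light zone program (3 peaks higher and 2 lower), 0.05 for memory precursor genes (4 and 4), 0.08 for migration receptors (3 and 1), 0.03 for antigen presentation (0 and 1) and -0.08 for AP-1 and immediate early factors (1 and 5). A light zone site inside Nfkb1, which encodes an NF-kB subunit, rose from 6.46 ± 0.741 to 12.7 ± 1.58 CPM (0.95), while another 26545 bp from that gene fell by 0.98. Markers of other cells that a spleen sort could hold had medians of -0.01 for T cells (1 peak higher and 3 lower of 62) and 0.05 for naive and follicular B cells (3 and 0 of 285). Medians were 0.06 for myeloid cells (1 and 3 of 54), -0.02 for erythroid cells (0 and 3 of 42) and -0.11 for natural killer cells (0 and 0 of 25). Adjusted over the list alone, the counts higher and lower in CB were 2 and 1 for the light zone, 0 and 3 for memory precursors, 3 and 0 for migration receptors, 0 and 1 for antigen presentation and 1 and 1 for AP-1. They were 1 and 3 for T cells, 0 and 0 for naive B cells, 1 and 3 for myeloid cells, 1 and 3 for erythroid cells and 1 and 2 for natural killer cells. The mean had the opposite sign to the median for the light zone, plasma cell, antigen presentation, cell cycle and myeloid lists. The gene-end peaks named in advance for Bcl6, Prdm1, Irf4, Myc, Cxcr4, Cd83, Cd86, Foxo1 and S1pr2, and the peak nearest Ccr6, did not pass the test in CB (adjusted p of 0.293 or more).

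Peaks were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, which passed 4.63% of the peaks in CB. Losses outnumbered gains less strongly with other models: 6329 peaks fell and 2768 rose with a replicate block (69.6% lower, against 83.2%), 5902 and 2223 with library size as a covariate, and 4787 and 2279 with Xist signal as a covariate. The count was 341 without HOMO CB 2, 693 without WT CB 1, 804 without HOMO CB 3, 4905 without both HOMO libraries numbered 1 and 1660 without both WT libraries numbered 2. Of 59 called peaks chosen by the naming rule, 22 kept their call whichever library was left out. Without HOMO CB 2 the adjusted p was 0.0614 and 0.0576 at the Ccnd3 sites, 0.114 at Foxp1, 0.0969 at Ebf1, 0.0787 at Usp18, 0.0836 at Ddx58, 0.104 at Sdc1, 0.061 at Pmaip1 and 0.128 at the lower Nfkb1 site. Without WT CB 1 it was 0.0578 at Nusap1 and 0.174 at Brd7. The B cell receptor list lost its call without HOMO CB 3 (adjusted p = 0.128). The AP-1 list was called lower without WT CB 1, WT CB 2 or HOMO CB 3 (adjusted p of 0.0362, 0.0465 and 0.0125), the migration list higher without WT CB 3 or HOMO CB 1 (0.0495 and 0.0218), and the interferon list lower without HOMO CB 3 (0.0239). With all libraries and an estimated correlation these 3 had adjusted p of 0.846, 0.719 and 0.384.

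In CC the knockout also had more losses than gains, with 1492 peaks lower and 397 higher, assigned to 1320 and 309 genes. The same peak inside Wdfy4 fell from 36.7 ± 3.66 CPM in WT CC to 12.5 ± 1.08 CPM in HOMO CC (log2 fold change -1.54, SE 0.14, adjusted p = 1.61e-05). Named losses away from chromosome 14 lay at an end of Zfp13, a zinc finger gene (14.2 ± 2.41 to 5.41 ± 0.862 CPM, -1.35), and inside Tnk2, the gene of a non-receptor tyrosine kinase (8.47 ± 0.683 to 3.42 ± 0.656 CPM, -1.37). Named gains lay inside Nfkb1 (4.62 ± 0.343 to 12.1 ± 0.77 CPM, 1.37) and inside Nsun3 (3.95 ± 0.9 to 10.7 ± 1.17 CPM, 1.42). Others lay inside Prex1, which encodes a Rac exchange factor (2.27 ± 0.147 to 6.46 ± 0.823 CPM, 1.49), and Csk, the kinase that restrains Src-family signalling (45.2 ± 3.08 to 64.9 ± 2.31 CPM, 0.53).

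In CC 4 lists were called higher by camera. Germinal center transcription factors had a median of 0.15 (8 of 633 peaks higher and 1 lower, adjusted p = 9.29e-05) and B cell receptor signalling 0.13 (4 higher and 1 lower of 428, adjusted p = 0.000345). The dark zone program had 0.10 (5 higher and 2 lower of 166, adjusted p = 0.0168) and migration receptors 0.08 (4 higher and 0 lower of 257, adjusted p = 0.036). None of these camera calls held with an estimated correlation (adjusted p of 0.467, 0.473, 0.0679 and 0.517 in that order). Fry, which does not compare a list with other peaks, gave adjusted p of 0.111, 0.166, 0.00187 and 0.258 in the same order. By fry the dark zone list alone of these passed. After subtraction of class and level medians the first 3 were smaller, at 0.077, 0.071 and 0.057 (camera adjusted p of 0.00779, 0.00893 and 0.0208). HOMO CC 1 did not share the shift of 3 of them. Its median deviation was -0.035 for transcription factors (WT CC libraries -0.095 to -0.011), -0.116 for B cell receptor signalling (-0.12 to -0.061) and -0.091 for migration receptors (-0.079 to 0.003). At gene-end peaks alone, set against all other peaks, the dark zone median was -0.05 (camera adjusted p = 0.188). Adjusted over the list alone, the counts higher and lower were 0 and 0, 1 and 1, 6 and 2, and 3 and 0. Peaks that rose included sites inside Ikzf3 (0.51) and 622 bp from Irf8 (0.53), both lymphoid transcription factors, inside Vav1, an exchange factor of antigen receptor signalling (0.86), and 139 bp from Itga4, an integrin subunit (0.48). A site at an end of Foxo1, a dark zone regulator, fell from 21.7 ± 1.67 to 14.8 ± 1.37 CPM (-0.54).

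Other lists in CC were not called with all libraries. BAF and PBAF subunit genes had 0 peaks higher and 4 lower, including Dpf1 (-1.27), Dpf2 (-0.90) and Ss18, another BAF subunit gene (-0.62). Over all peaks 2.75% were called in CC, and 79.0% of those calls were lower. Interferon genes had 1 peak higher, 8059 bp from the antiviral gene Ifitm3 (0.68), and 6 lower, including an end of Xaf1 (-1.01). Medians were 0.07 for the light zone program, 0.09 for memory precursors, 0.05 for plasma cells, 0.03 for the BAF and PBAF subunits, -0.02 for interferon, 0.04 for antigen presentation, 0.05 for the cell cycle and -0.02 for AP-1. Among markers of other cells they were -0.09 for T cells, 0.10 for naive B cells, 0.05 for myeloid cells, 0.05 for erythroid cells and -0.07 for natural killer cells. The myeloid and erythroid means had the opposite sign to their medians.

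The test passed 2.75% of the peaks in CC. With a replicate block 4534 peaks fell and 2607 rose (63.5% lower, against 79.0%), with library size as a covariate 3922 and 1860, and with the Xist covariate 3051 and 1895. The count was 17 without HOMO CC 2, 219 without HOMO CC 3, 330 without WT CC 1, 601 without WT CC 2, 1018 without WT CC 3 and 3413 without HOMO CC 1. It was 325 without both WT libraries numbered 2, and DESeq2 called 3113. Of 52 called peaks chosen by the naming rule, 11 kept their call whichever library was left out, among them those at Wdfy4, Nfkb1, Nsun3, Prex1 and Zfp13. Without HOMO CC 2 the adjusted p was 0.0743 at Csk, 0.0573 at Tnk2, 0.0743 at Dpf1, 0.111 at Dpf2, 0.107 at Ss18, 0.0963 at Itga4, 0.112 at Ikzf3, 0.199 at Irf8 and 0.131 at Ifitm3. It was 0.116 at Vav1 and 0.115 at Xaf1 without HOMO CC 3, and 0.134 at Foxo1 without WT CC 1. The migration list lost its call without WT CC 1, WT CC 2, HOMO CC 2 or HOMO CC 3 (adjusted p of 0.124, 0.191, 0.294 and 0.122), and after subtraction of class and level medians (0.139). That subtraction gave a call to the AP-1 list, lower in CC (median -0.08, adjusted p = 0.0444), as did leaving out HOMO CC 3 (0.019). Without WT CC 3 or HOMO CC 1 the light zone list (adjusted p of 0.00268 and 0.00204) and memory precursors (0.0289 and 0.0165) were called higher, and naive B cell markers were without WT CC 3 (0.0135) or HOMO CC 3 (0.0322). With all libraries and an estimated correlation the AP-1, light zone, memory and naive B cell lists had adjusted p of 0.846, 0.686, 0.655 and 0.511.

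The genotype effects in the 2 populations were then compared directly. Of the peaks called higher in CB, 173 were also called higher in CC, where independent lists would share 3.09. Of those called lower, 1086 were shared, where independent lists would share 57.4. The number called in opposite directions by edgeR was 0, and 98.7% of the higher and 99.7% of the lower CB calls had the same sign in CC. Across all peaks, which are not independent replicates, the effects correlated with Pearson's r = 0.72. Same-numbered CB and CC libraries of a genotype varied together (correlations of 0.21 to 0.52 in 6 pairs), and neither these expectations nor the r allow for that. The test of the difference itself called 0 peaks with edgeR and 0 with DESeq2, with 810 peaks at an unadjusted p under 0.05, and 0 of the 17 lists by camera. The light zone list (median difference 0.08, adjusted p = 0.194) was called higher with a replicate block (adjusted p = 0.0273) and with a block by genotype and number (0.0196), while with an estimated correlation and no block its adjusted p was 0.891. It was also called without WT CB 2, WT CC 3, HOMO CB 3 or HOMO CC 1 (adjusted p of 0.0418, 0.00185, 0.00919 and 9.13e-05). The AP-1 list was called higher without WT CC 3 (0.00213) or HOMO CC 1 (0.00441), and B cell receptor signalling without HOMO CC 1 (0.00441), each at 0.891 with all libraries and an estimated correlation. The smallest p-values of the difference lay inside Dock10 (difference 1.28), near Ripk2 (0.90), inside Sorbs3 (1.16), inside Riok3 (-1.83), near Lfng (-0.96) and inside 1700094D03Rik (-1.10), all with an adjusted p of 1. The median standard error of a difference was 0.28, against 0.20 for a genotype effect.

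The lost peaks gathered at gene ends. Peaks within 1 kb of either end of a protein-coding gene made up 23.3% of all peaks and 55.6% of the peaks lower in CB (odds ratio 4.43, 95% interval 4.09 to 4.8, Fisher's exact test p = 6.94e-292). They made up 60.1% of those lower in CC (odds ratio 5.17, 4.65 to 5.75, Fisher's exact test p = 8.57e-207). Among the peaks that rose, gene ends made up 7.66% in CB and 8.06% in CC. These tests treat peaks as independent, which they are not. At peaks with an average log2 CPM of 2 to 5, the median deviation of gene-end peaks minus that of other peaks was 0.14 ± 0.10 in WT CB and -0.08 ± 0.07 in HOMO CB (log2 scale, mean ± SD, n = 3). In CC it was 0.08 ± 0.07 and -0.14 ± 0.07. A two-sided exact permutation test gave p = 0.1 in each population, the smallest p this design allows. The share of all counts at gene ends was 45.5% ± 1.68 in WT CB and 43.8% ± 0.787 in HOMO CB (exact permutation p = 0.3), and 44.6% ± 1.12 and 43.0% ± 0.514 in CC (exact permutation p = 0.1). Without HOMO CC 2, gene ends made up 27.3% of the 11 peaks lower in CC. The median log2 fold change in CC of gene-end peaks minus that of others, at log2 CPM of 2 to 5, was then -0.19, against -0.23 with all libraries.

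**Figure D2:**
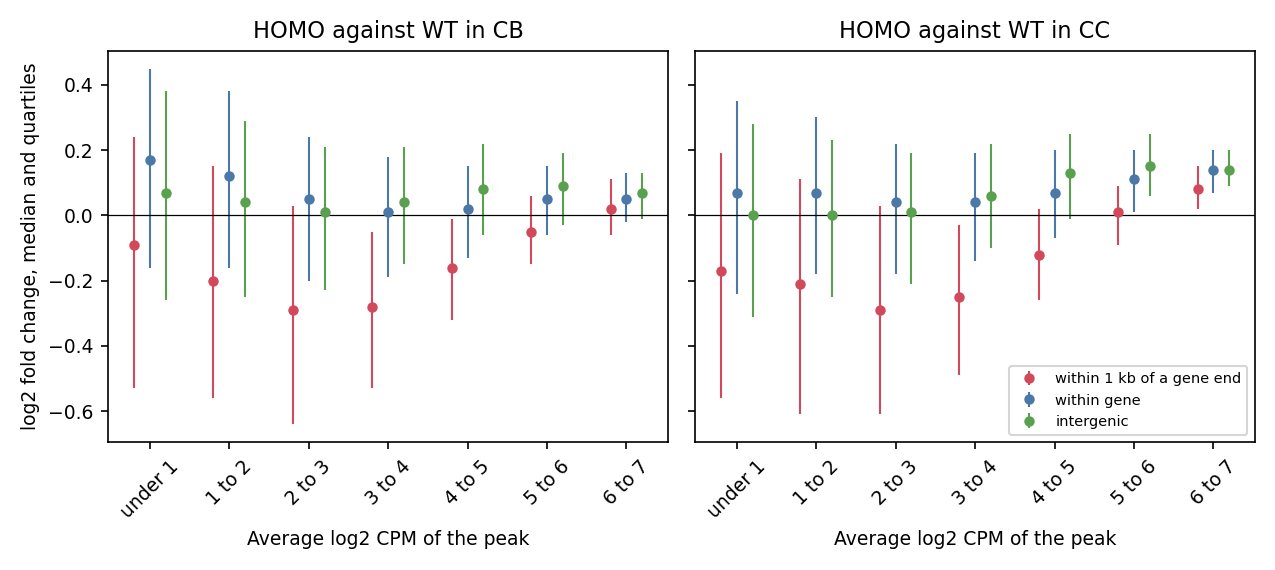
Log2 fold change of HOMO against WT (vertical axis) by average log2 CPM of the peak (horizontal axis, bins of 1; 22 gene-end peaks above the last bin are not drawn) for peaks within 1 kb of a gene end, elsewhere within a gene span, and intergenic; points are medians over peaks and bars run from the lower to the upper quartile. Between log2 CPM of 2 and 3 the gene-end median was -0.29 in both CB and CC.

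A second concentration of changes lay around Pbrm1 itself. Within 6 Mb of the gene on chromosome 14, 61 of 453 peaks were called in CB (13.5%), against 4.54% on the other chromosomes, and 44 were called in CC (9.71% against 2.71%). They went both ways, with 11 higher and 50 lower in CB. A second site in Wdfy4 rose (33099036 to 33099536, 2.28 ± 0.498 to 8.86 ± 1.49 CPM in CB, log2 fold change 2.02). A site inside 3425401B19Rik fell from 5.97 ± 1.13 to 0.454 ± 0.0626 CPM (32694296 to 32694796, -3.76), and a site inside Colq, which encodes the collagen tail of acetylcholinesterase, from 5.18 ± 1.43 to 0.817 ± 0.39 CPM (31535661 to 31536161, -2.91). Sites 5553 bp from Fam25c (0.851 ± 0.557 to 7.57 ± 1.76 CPM, 2.94) and 4592 bp from Wapl, a cohesin release factor (3.06 ± 1.63 to 18.2 ± 0.39 CPM, 2.49), rose. In windows of 5 Mb along the genome, the one from 30 to 35 Mb held 43 called peaks of 289 in CB, the smallest adjusted p of 453 windows (8.83e-09 with a test that treats peaks as independent).

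**Figure D3:**
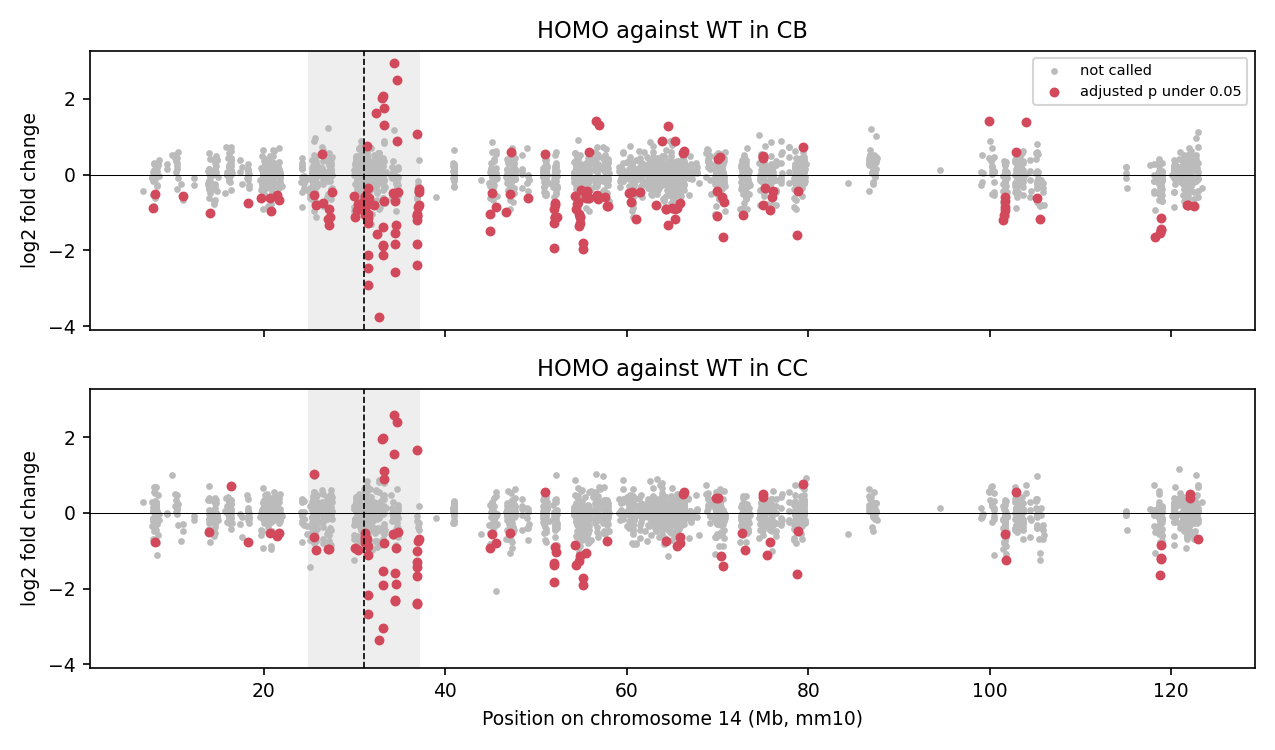
Log2 fold change of HOMO against WT in CB (top) and CC (bottom) for each peak (points) along chromosome 14 in Mb; red points passed an adjusted p of 0.05, the dashed line marks Pbrm1 and the grey band the 6 Mb on either side. The band holds 61 called peaks in CB and 44 in CC, with changes both up and down.

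The populations themselves were compared within each genotype. In WT, 2301 peaks were more open in CC and 1431 in CB. Peaks more open in CC included sites inside Pole, the catalytic subunit gene of a replicative DNA polymerase (4.5 ± 0.808 CPM in CB and 13 ± 0.879 CPM in CC, log2 fold change 1.5), and at an end of the potassium channel gene Kcnk10 (3.84 ± 0.442 and 11.8 ± 1.69 CPM, 1.64). Sites inside Acot12 (2.05) and Txndc11 (1.77) were also among them. Peaks more open in CB included sites 5649 bp from Tef, a clock-controlled transcription factor gene (23.6 ± 2.14 and 7.01 ± 0.652 CPM, -1.75), and inside Cplx2, the gene of an exocytosis regulator (17.1 ± 1.44 and 5.12 ± 0.944 CPM, -1.73). Sites inside Slc39a11, which encodes a zinc transporter (-1.45), and 8672 bp from Ifitm3 (-1.16) were others.

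Most lists had peaks of both kinds in WT. Light zone genes had 16 peaks more open in CC and 6 in CB of 269. Those more open in CC included a site 3710 bp from the proto-oncogene Myc (4.23 ± 0.278 and 9.69 ± 0.992 CPM, 1.18) and a site inside Bcl2l1, which encodes the survival protein Bcl-xL (7.21 ± 0.348 and 15 ± 0.284 CPM, 1.06). A site inside Cd40, the receptor for T cell help, was more open in CB (13.8 ± 1.52 and 5.5 ± 1.42 CPM, -1.29). Dark zone genes had 7 and 8 of 166, with Gcsam, a germinal center marker, more open in CB (-0.86) and Nusap1 in CC (2.42). Transcription factor genes had 39 and 28 of 633. A site inside Pax5, the B cell identity gene, was more open in CB (19 ± 2.88 and 8.6 ± 0.969 CPM, -1.13), and a site inside Bach2, a repressor of plasma cell fate, in CC (2.31 ± 0.476 and 7.52 ± 0.937 CPM, 1.65). Memory precursor genes had 25 and 9 of 319 (Celf2, 2.04) and naive and follicular B cell genes 20 and 4 of 285 (Foxp1, 1.37).

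Peaks of B cell receptor signalling were lower in CC as a set in WT (median -0.10, 10 higher and 15 lower of 428, camera adjusted p = 0.0399). That call was lost with an estimated correlation (adjusted p = 0.771), and without WT CB 1, WT CC 1 or WT CC 2 (adjusted p of 0.196, 0.071 and 0.149). Adjusted over the list alone, 10 were higher and 18 lower. Those lower included a site 1917 bp from the inhibitory receptor gene Cd22 (-0.97), while the kinase gene Blk was more open in CC (1.6). No other list was called by camera in WT. The counts more open in CC and in CB were 4 and 6 for plasma cell genes, 5 and 11 for BAF and PBAF subunits, 1 and 3 for interferon genes and 7 and 13 for migration receptors. They were 7 and 3 for the cell cycle, 3 and 0 for AP-1 factors and 0 and 0 for antigen presentation. Markers of other cells had 0 and 0 of 62 for T cells, 5 and 2 of 54 for myeloid cells (Itgax 2.74), 2 and 0 of 42 for erythroid cells and 2 and 0 of 25 for natural killer cells (Tbx21 1.22). Median and mean had opposite signs for the light zone, dark zone, transcription factor, migration, cell cycle, AP-1 and T cell lists. The peak nearest Ccr6, a memory precursor marker, was more open in CC (9.79 ± 1.71 and 15.5 ± 1.17 CPM, 0.67, adjusted p = 0.0362), and reached an adjusted p of 0.199 without WT CB 1. The gene-end peaks named above for CB did not pass the test in WT.

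**Figure D4:**
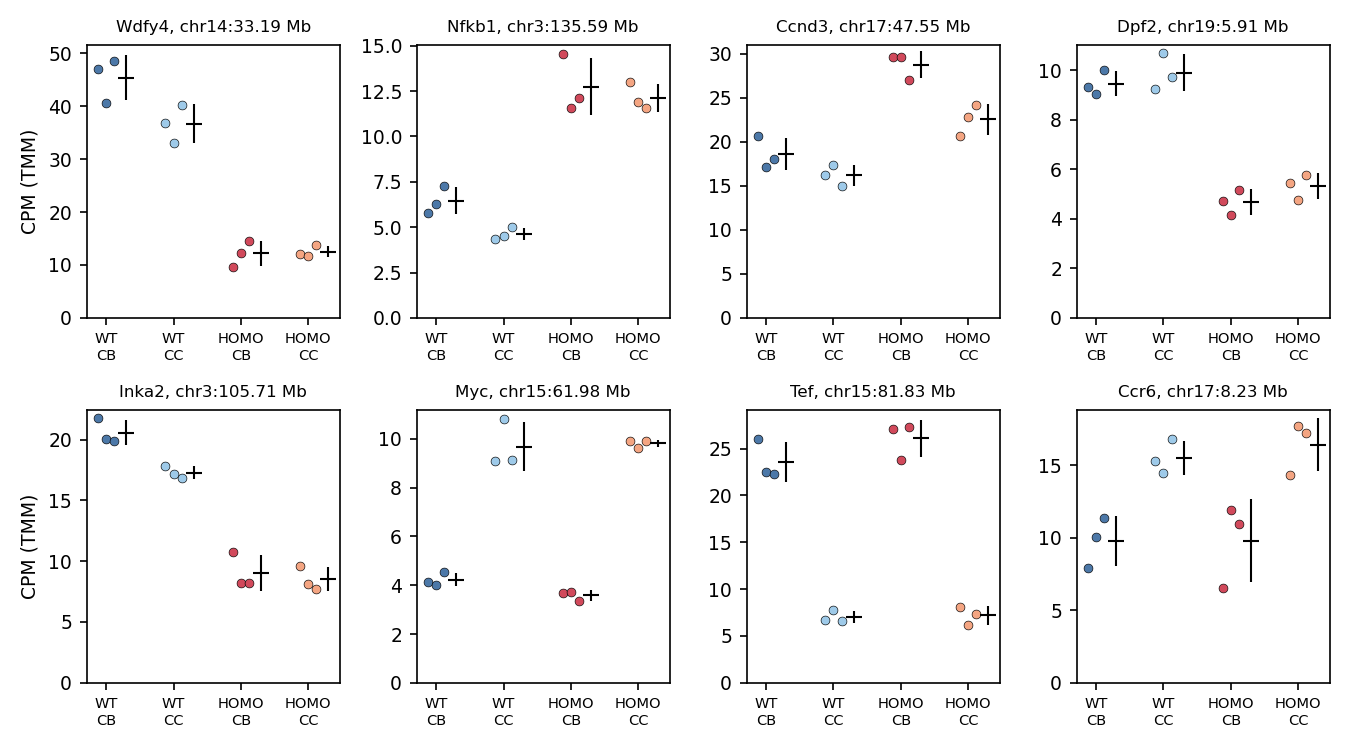
CPM with TMM factors at 8 named peaks in each group; points are the 3 libraries and the bar beside them the mean ± SD, and each axis starts at 0. Sites at Wdfy4, Dpf2 and Inka2 were lower and those at Nfkb1 and Ccnd3 higher in HOMO libraries, while those at Myc, Tef and Ccr6 separated CC from CB, with WT values of 4.23 and 9.69 CPM in CB and CC at Myc.

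Same-numbered CB and CC libraries of a genotype varied together, so the paired fit is given beside these counts. It called 15211 peaks in WT, 7126 more open in CC and 8085 in CB. Scaling to library size alone gave 2989 and 918 unpaired. The unpaired count was 1301 without WT CB 1, 2052 without WT CB 2, 2019 without WT CC 1, 1569 without WT CC 2 and 527 without both WT libraries numbered 2. Of 57 called peaks chosen by the naming rule, 44 kept their call whichever library was left out, and those described above other than Ccr6 were among them.

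In HOMO, 3284 peaks were more open in CC and 1673 in CB, and the paired fit called 8612 and 6652. Of the sites more open in CC, 1623 were called in both genotypes, where independent lists would share 110, and of those more open in CB 915, where 34.9 would be shared. At the sites named for WT, HOMO CB and CC had 3.58 ± 0.214 and 9.82 ± 0.152 CPM near Myc, 26.1 ± 1.99 and 7.21 ± 1 CPM near Tef and 15.3 ± 2.26 and 7.14 ± 0.569 CPM in Cd40. Light zone genes had 26 peaks more open in CC and 7 in CB, dark zone genes 7 and 13, memory precursor genes 35 and 8, and naive B cell genes 30 and 10. No list was called by camera in HOMO with all libraries, the smallest adjusted p being 0.188 for memory precursor genes. After the median of peaks of the same class and level was subtracted, the light zone, memory precursor and AP-1 lists were called higher in CC (adjusted p of 0.0355, 0.0362 and 0.0362). Without the subtraction and with an estimated correlation they had adjusted p of 0.858, 0.858 and 0.873. The same 3 were called without HOMO CC 1 (0.0095, 0.00912 and 0.0266), and memory precursors without HOMO CB 2 (0.0166). B cell receptor signalling was called lower in CC without HOMO CB 1 (0.0296) or HOMO CC 3 (0.0328), against 0.858 with all libraries and an estimated correlation. Gene ends made up 3.78% and 9.36% of the peaks higher and lower in CC in WT and 5.48% and 8.07% in HOMO. The unpaired HOMO count was 2018 without HOMO CC 2, 2458 without HOMO CB 3 and 2975 without HOMO CB 2.

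The last comparison set the genotype effect beside the difference between CC and CB. Across all peaks the genotype effect in CB correlated with the difference between CC and CB in WT at r = 0.143. The WT CB libraries that both effects share gave 0.274 ± 0.00444 with no genotype effect (mean ± SD of 100 simulations), with covariances of 0.0219 observed and 0.0292 simulated. In CC the correlation was -0.126 against -0.257 simulated, with covariances of -0.0175 and -0.0271. The simulated libraries were drawn independently, and the deviations that same-numbered CB and CC libraries share would by themselves bring both covariances nearer to 0, so these gaps do not measure a genotype effect. The average genotype effect against the average difference between CC and CB gave r = -0.03 (0.0102 ± 0.00451 simulated). Both averages use all libraries, and the tie this gives cancels only where the groups are equally noisy. The simulated value shows that little of it was left. Peaks more open in CC in WT had a median genotype effect of 0.10 in CB and 0.01 in CC, and those more open in CB had 0.07 and 0.14. The 0.01 became -0.02 with scaling to library size alone. When the peaks were instead chosen in HOMO, the medians in CB were -0.15 and 0.14, so the sign in CB depended on which genotype chose the peaks for those more open in CC and not for those more open in CB. Libraries that chose the peaks also enter the genotype effect, which by itself moves these medians. No values without a genotype effect were computed for them, so their signs do not tell the direction of the effect.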

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

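Of the tests in this part, those of flanking strain DNA, of enrichment at strong gene-end peaks and of the other splits of the libraries were chosen after the results were seen, as were the fits with library size, thinned counts and Xist and the subtraction of class and level medians. The 6 Mb zone around Pbrm1 was not in the plan fixed beforehand. Nor was the contrast of gene-end with other peaks at log2 CPM of 2 to 5, with its permutation test. At 6 named peaks every HOMO library lay on 1 side of the WT mean in CB and on the other side in CC. This pattern of signs was not tested, and the test of the difference of effects gave each an adjusted p of 1. The differences were -0.96 at Itgax (peak_29349), -1.26 at Klre1 (peak_25042), 1.16 at Sorbs3 (peak_53989), -0.96 at Lfng (peak_21317), -1.10 at 1700094D03Rik (peak_11730) and 0.17 at Cd86 (peak_59110).

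Genotype calls gathered around Pbrm1 on chromosome 14. A difference in depth was set against them: with counts thinned to the shallowest library, the called share within 6 Mb was still 4.59 times that on other chromosomes, which argues against depth as the whole cause. With library size as a covariate the ratio was 1.94 in CB and 2.06 in CC, since calls rose both within 6 Mb (13.5% to 22.7% in CB) and on other chromosomes (4.54% to 11.8%), and the Xist covariate gave 1.99 and 2.01. As a hypothesis, DNA of another strain may flank the targeted allele: large changes were 3.71 times as frequent within 6 Mb as more than 20 Mb away on the chromosome, and the CB and CC effects correlated at 0.89 within 6 Mb against 0.71 on other chromosomes. The frequency was counted in the zone where calls had already been seen to gather, so it restates that gathering and is no separate test of this hypothesis. An effect of the lost gene on its own neighbourhood would give the same close correlation (0.89), so the 2 cannot be told apart from these values.

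Gene ends held 55.6% of the peaks lower in HOMO CB and 60.1% of those lower in HOMO CC (27.3% of 11 peaks without HOMO CC 2), against 23.3% of all peaks. Without HOMO CC 2 the gene-end minus other difference in CC was -0.19, against -0.23 with all libraries (log2 CPM of 2 to 5). Neither depth nor a trend with signal level removed this: at log2 CPM of 2 to 5 gene-end peaks minus others in CB differed by -0.24 with library size as a covariate, -0.22 with thinned counts and -0.23 with loess offsets. Lower enrichment at every gene end in HOMO libraries was tested on peaks of log2 CPM 6 or more, where 1251 gene-end peaks differed from 348 others by -0.05 (SE 0.024). That test first used the median of the strong gene-end peaks alone, which was 0.02 and spoke against lower enrichment, and was replaced by the difference after that value was seen. Lower enrichment therefore stays open, and an effect of the genotype may be weighed only as a hypothesis beside it.

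The dark zone and transcription factor lists were higher in HOMO CB. After the median of peaks of the same class and level was subtracted, the dark zone median was 0.123 (SE 0.03, camera adjusted p = 0.000413), which argues against class and level as the whole cause, and in CC 0.057 (SE 0.025, camera adjusted p = 0.0208), where the unsubtracted call was lost with an estimated correlation (adjusted p = 0.0679). The 0.123 in CB exceeded the bound of 0.1 set beforehand by less than its SE. Reading it against class and level therefore also uses the later rule given below for transcription factors. The standard errors in this paragraph treat peaks as independent, which they are not, and do not measure the spread between libraries. After subtraction camera used test statistics with class and level means removed, at the preset correlation. At gene-end peaks alone the dark zone list had a median of -0.10 in CB (camera adjusted p = 0.148). That test compared with all other peaks, and gene-end peaks were lower as a class, so it cannot tell whether the list's shift held at gene ends. For transcription factors the subtracted median in CB was 0.093 (SE 0.013, camera adjusted p = 0.00331), under the bound of 0.1 set beforehand, so reading it against class and level rests on a call kept with the preset correlation, a rule settled after the values were seen, while the unsubtracted call was lost with an estimated correlation (adjusted p = 0.652). With Xist signal as a covariate the dark zone median was 0.18, which argues against the sex make-up of the libraries as its cause, and a biological effect on these genes stays a hypothesis.

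The 6 libraries of each comparison of 3 against 3 have 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many peaks, with real counts of 3178, 1889, 3732 and 4957 in CB, CC, WT and HOMO and a highest other of 0 for each (edgeR; counts at unadjusted p and by DESeq2 were not taken for other splits). For the difference of effects the real count was 0 (810 at an unadjusted p under 0.05, and 0 by DESeq2). All 100 of 100 splits, the real one among them, therefore gave as many by definition, so their number decides nothing. The highest other count was 4351, from a split that kept the genotypes apart in CB and parted CC into WT 1, WT 2 and HOMO 1 against WT 3, HOMO 2 and HOMO 3. The other split with any call (1509) also kept the genotypes apart in CB and mixed them in CC. The genotype effect in CB, a structure of the samples, thus enters the tested difference in both, though other splits of that kind called 0.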

How the results depend on the processing

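The fits with library size as a covariate, thinned counts, libraries numbered 1 or 2 left out, chromosome 14 left out, the Xist covariate, the subtraction of class and level medians and the average effects were chosen after the data were examined. More peaks fell than rose with genotype in CB and in CC in every alternative. The difference of effects called 0 peaks in every edgeR alternative and with DESeq2 (810 at an unadjusted p under 0.05). GC and motif alternatives were not run. The table of named peaks gave 4890 comparisons: 4374 kept direction and call, 469 lost the call, 3 gained one and 44 turned direction, none of the last called. Counts below are for the genotype effect in CB, in CC, and CC against CB in WT and HOMO, in that order. Thinned counts hold fewer reads by construction. Leaving out libraries lowered some counts and raised others, and there and elsewhere the cause was not tested.

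At an adjusted p under 0.01 the counts were 692, 186, 1181 and 2003, and with a log2 fold change of at least 1 they were 777, 472, 1689 and 2157. DESeq2 gave 3113 in CC, and limma voom 6336 in CB and 3939 in CC. A replicate block gave 9097, 7141, 8749 and 9897, a block by genotype and number 15211 in WT and 15264 in HOMO, and the block as a random effect 7094, 4846, 13658 and 16195. Library size as a covariate gave 8125, 5782, 7858 and 8993, and thinned counts 985, 490, 1822 and 2668. Without both HOMO libraries numbered 1 there were 4905 in CB and 4442 in CC. Without both WT libraries numbered 2 there were 1660, 325 and, in WT, 527. The Xist covariate gave 7066, 4946 and, in WT, 6124. Loess offsets gave 756 higher and 2440 lower in CB. Leaving out 1 library gave 341 (HOMO CB 2) to 3722, 17 (HOMO CC 2) to 3413, 1301 (WT CB 1) to 3565 and 2018 (HOMO CC 2) to 4677.

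Lists called numbered 3 in CB, 4 in CC, 0 for the difference, 1 in WT and 0 in HOMO by camera. An estimated correlation gave 1 in CB, 0 in CC and 0 in WT, and gene-end peaks only 1 in CB and 2 in CC. The difference had 1 with the replicate block and 1 with the paired block. WT had 0 with genes within 100 kb and 0 after subtraction of class and level medians, which gave HOMO 3. Leaving out 1 library gave 3 to 4 in CB, 3 to 7 in CC (7 without WT CC 3), 0 to 3 for the difference (3 without HOMO CC 1), 0 to 1 in WT and 0 to 3 in HOMO (3 without HOMO CC 1). On gene-end peaks only, the dark zone list turned to lower in CB (adjusted p = 0.148) and CC (0.188) and the migration list in CC (0.871), none called. These gene-end tests compared with all other peaks, and gene-end peaks were lower as a class, so they do not separate a list from that class.

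The correlation along the axis was -0.0304 for the average effects, against 0.143 in CB and -0.126 in CC. With peaks chosen in HOMO the median genotype effect in CB was -0.15 for peaks higher in CC and 0.14 for those lower, and in CC 0.02 for those lower. With library size only it was -0.02 in CC for peaks higher in CC.

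Named peaks that turned were Pbrm1, Bcl6, Irf4, Myc, Cxcr4, Cd83, Cd86, Foxo1, S1pr2 and Ccr6, all uncalled where they turned. Thinned counts gave 0.14 at Pbrm1, -0.02 at Myc and 0.03 at Cd83 in CB, and -0.06 at Myc and -0.06 at Foxo1 in WT. Without both HOMO libraries numbered 1 Pbrm1 had 0.04 in CB. Without both WT libraries numbered 2 the values in WT were -0.08 at Pbrm1, -0.11 at Irf4 and -0.01 at Myc. Library size as a covariate gave -0.01 at Myc and -0.03 at Ccr6 in CB. The Xist covariate gave -0.02 at Bcl6 in CC, and 0.04 at Cd86 and -0.05 at S1pr2 in CB. Cd83 in WT had 0.01 with library size only and 0.06 with loess offsets. Leaving out 1 library ranged in CB from -0.17 to 0.16 at Pbrm1, -0.19 to 0.12 at Irf4, -0.11 to 0.10 at Myc, -0.13 to 0.02 at Cd83, -0.26 to 0.01 at Cd86 and -0.09 to 0.22 at Ccr6. In CC it ranged from -0.26 to 0.09 at Pbrm1, -0.07 to 0.22 at Bcl6, -0.05 to 0.11 at Irf4, -0.09 to 0.19 at Myc, -0.05 to 0.12 at Cxcr4 and -0.10 to 0.01 at Foxo1. In WT it ranged from -0.16 to 0.22 at Pbrm1, -0.04 to 0.23 at Irf4, -0.04 to 0.06 at Myc, -0.20 to 0.03 at Cd83 and -0.04 to 0.05 at Foxo1.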

Other observations

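The test by windows of the genome was chosen after the results were seen. Some peaks of other groups also differed by genotype. A site inside Cd247, which encodes the zeta chain of the T cell receptor complex, fell in CB (19.1 ± 1.53 to 9.3 ± 0.681 CPM, log2 fold change -1.05, n = 3) and kept its call whichever library was left out. It fell in CC (-0.97) but had an adjusted p of 0.0743 without HOMO CC 2. An end of B2m, the light chain gene of MHC class I, fell in CB (28.9 ± 2.43 to 20.1 ± 2.05 CPM, -0.55, adjusted p up to 0.117 without HOMO CB 3). Sites 22136 and 22691 bp from Cxcr4, the dark zone chemokine receptor gene, rose in CB (0.59 and 0.61), with adjusted p of 0.0938 and 0.141 without HOMO CB 2. Besides the window at Pbrm1, the 5 Mb from 155 to 160 Mb of chromosome 4 held 18 called peaks of 114 in CB (adjusted p = 0.00119) and 13 in CC (adjusted p = 0.00252), and that from 120 to 125 Mb of chromosome 6 held 24 of 209 in CB (adjusted p = 0.00663) and 20 in CC (adjusted p = 0.000387). In CB the windows starting at 65 Mb of chromosome 13, 120 Mb of chromosome 2, 15 Mb of chromosome 16 and 50 Mb of chromosome 14 also passed (adjusted p of 0.0207, 0.022, 0.022 and 0.022), and in CC that starting at 25 Mb of chromosome 17 (adjusted p = 0.0187). Windows also passed for CC against CB in WT, among them those starting at 30 Mb of chromosome 4 (adjusted p = 0.00177) and 15 Mb of chromosome 9 (adjusted p = 0.00233). Passing windows are thus not particular to the genotype effects. The test treats peaks as independent, which they are not.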
